A study of Mus musculus with 14 samples.

How the data were processed

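The study measured RNA from the hypothalamus of 10-week-old male C57BL/6N mice that were fed either a control diet (NCD) or, during 3 days, a diet rich in fat (HFD). Per the labels, hypothalami were pooled, 8 to a pool. Part of each lysate was kept as input. Ribosomes carrying phosphorylated S6, a ribosomal protein that is phosphorylated in activated cells, were precipitated with an antibody from the rest (IP). RNA of both fractions was amplified before library preparation with a kit that primes with poly(T) and random primers, and the library kit does not mark the strand. The 14 libraries fall into 4 groups: 3 input and 3 IP libraries on control diet, and 4 input and 4 IP libraries on high-fat diet. The labels speak of 4 precipitations per condition, of which 3 control-diet ones were used here.

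One table was used, with 14531 entries, 1 per gene or gene model. Its deposited values for the 14 libraries are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), called normalized by the authors, who do not state how libraries were scaled to each other. The authors also list, per the file headers, a ratio (fold) of IP to input FPKM for each of 7 pairs of columns, a deposited p-value that is not adjusted for multiple tests, and a deposited log2 of the mean high-fat ratio over the mean control ratio. Per the submitters' processing notes, HISAT2 2.1.0, StringTie 1.3.4d, Cufflinks 2.2.1 and Cuffdiff were used on the mouse genome build GRCm38.p6, with no role or order stated for each. The columns carry an index from 0 to 3 in place of the replicate numbers of the labels, so columns were assigned to groups and not to single labelled samples, and single libraries are named here by group and index. The IP to input ratios were checked to be the quotient of the columns with the same diet and index in all 96385 entries that hold one (relative tolerance 0.001), and the deposited p-values were checked to follow in all 14531 entries from an unequal-variance comparison of the ratios.

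All comparisons started from the FPKM as deposited. Genes with a mean FPKM of at least 1 over the 14 libraries were tested (12484 of 14531 entries), where a symbol with several entries was represented by the one with the highest mean. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3 with a trended empirical Bayes variance. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 12484 genes, with a threshold of 0.05. Log2 changes are given with their standard error from limma (±), and FPKM as mean ± SD. A log2 change of 1 is a 2-fold change, and on this scale changes of genes near or below 1 FPKM are understated. The diet comparison was fitted within each fraction. The comparisons of IP with input and the difference of the diet effects used 1 fit of the 4 group means over all 14 libraries. The p-values of single genes measure spread between libraries, each from 1 pool. IP and input libraries were fitted as independent, although both fractions came from the same lysates.

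For each comparison, 34 of 36 gene lists (pathways, cell type markers and markers of neighbouring brain regions) had at least 5 tested members and were tested with camera from limma, which compares a list's genes with all other genes, at a preset correlation of 0.01 between genes. At that setting its p-value rests on the spread of changes between genes and not only on spread between pools. The adjusted p with the correlation estimated from the data is given beside each call. A list's level in a library is the mean log2(FPKM + 1) of its members, and differences in level between diets were tested by exact permutation over the 35 splits of 7 libraries into 3 and 4, for which the smallest p is 0.0286. The comparisons, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule names, per comparison, up to 10 genes in each direction with the largest change among genes past the threshold whose groups do not overlap in any library. Where fewer pass, it names 5 per direction with the smallest p and no overlap, given as values that did not pass. It adds up to 4 members with the smallest p of each list described, and, in the diet comparisons, Pnoc, Fos, Agrp, Npy, Pomc and Cartpt. A few genes that the rule names are not reported. Gene models without a usual symbol are counted but not named, unless a count is so small that its gene is singled out.

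The number of reads behind each value is unknown, so no counting intervals or detection limits are given. Positions, strands, transcript lengths and base composition came from GENCODE M21, matched by Ensembl identifier for 12478 of 12484 tested genes. The pipeline was tested on simulated data with the spread of these libraries. In the simulated IP diet comparison, 0 of 61 genes changed 2-fold, 8 of 71 genes changed 4-fold (11.3%) and 19 of 68 genes changed 8-fold (27.9%) were recovered, with 3 false calls among 30 calls. In the simulated input diet comparison, 43 of 64 genes changed 2-fold were recovered (67.2%), with 11 false calls among 176 calls. In simulations of the fit over both fractions, false calls were 12 of 58 for the difference of the diet effects. They were 22 of 127 for IP against input over both diets, 16 of 114 on high-fat diet and 7 of 83 on control diet. With a replicate block they were 1 of 23, 8 of 101, 5 of 72 and 0 of 46, in that order. Without that block, as used here, genes called by this fit can therefore include more false calls than the threshold allows. Alternatives were another pseudocount (0.1), no filter, a filter of 5 FPKM, median-ratio scaling, quantile normalization, robust empirical Bayes, array weights, a replicate block, another set of libraries in the fit, and leaving out each library. After the data were examined, fits without the IP libraries of index 0, fits with FPKM below 0.001 as missing, a block on the column index in the diet comparisons and 2 alternatives for list levels were added. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.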

Results

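RNA was compared between 7 input libraries, which hold the RNA of whole hypothalamic lysate, and 7 IP libraries, made with an antibody against phosphorylated S6. RNA carried along without such ribosomes cannot be told apart, since no precipitation with a control antibody was analysed here. Each library came from 1 pool of 8 hypothalami, with 3 pools on control diet and 4 pools on high-fat diet in each fraction. The title of the series states its subject as activated hypothalamic cells during acute high-fat feeding. The table gives FPKM and the read depth is unknown.

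Input libraries resembled each other closely, and IP libraries varied more. The correlation across genes between libraries of a group was 0.970 to 0.981 in input on high-fat diet and 0.971 to 0.979 in input on control diet. It was 0.823 to 0.917 in IP on high-fat diet and 0.720 to 0.830 in IP on control diet, where genes are not independent replicates. Mitochondrially encoded genes took 23.5% to 39.1% of summed FPKM in input and 2.66% to 15.6% in IP. Of the 14531 entries, 0.282% to 0.957% were listed at 0 in input libraries and 0.771% to 10.9% in IP libraries. The IP libraries of index 0 held the largest shares of both kinds within IP, with 12.8% mitochondrial FPKM and 9.57% of entries at 0 on high-fat diet and 15.6% and 10.9% on control diet.

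**Figure D1:**
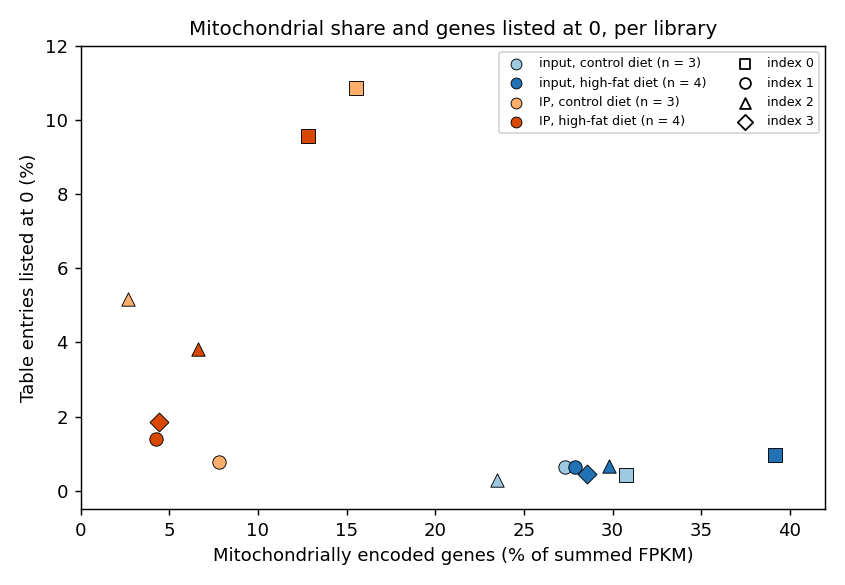
Each point is 1 library, with the share of summed FPKM from mitochondrially encoded genes (%) on the x axis and the share of table entries listed at 0 (%) on the y axis. Color gives the group and shape the column index. Input libraries lie at 23.5% or more mitochondrial FPKM, and the 2 IP libraries of index 0 (squares) lie above all others in entries at 0, at 9.57% and 10.9%.

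Comparing IP with input over both diets shows which RNAs the precipitation held. Messages of the translation machinery and of mitochondrial energy metabolism were enriched with the smallest p of the 34 lists, of which the former did not pass with an estimated correlation (adjusted p = 0.19) and the latter did (adjusted p = 0.0050). All 76 measured cytosolic ribosomal protein genes were higher in IP, with a median log2 change of 3.01. Of 68 nuclear genes of oxidative phosphorylation, 57 were higher, 0 were lower and 11 did not pass, with a median of 1.94 (1.12 with quantile normalization). Mitochondrially encoded genes and markers of mature oligodendrocytes and astrocytes were lower in IP, as lists at the preset correlation of camera and not with an estimated one. Of 12484 genes tested with limma, 5482 passed the threshold (43.9%), 2926 higher and 2556 lower in IP. The share of called genes that were higher was 48.0% with median-ratio scaling and 45.2% with quantile normalization, so the majority turned. Over all 12484 genes, the groups did not overlap within either diet in 3090 (24.8%), where chance gives 0.143%. Of these genes, 3075 were past the threshold.

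Among single genes, Selenow, which encodes a small selenoprotein, rose most. Its FPKM was 14.3 ± 6.80 (SD, n = 3) in input and 942 ± 392 in IP on control diet, and 15.0 ± 9.42 and 1032 ± 441 (n = 4) on high-fat diet, a log2 change of 6.03 ± 0.30 (adjusted p = 9.8e-10). It lies on chromosome 7 at 15917208 to 15922402 (GRCm38). The ribosomal protein genes Rpl29 (5.37 ± 0.19), Rps21 (5.18 ± 0.31), Rps19 (4.77 ± 0.21), Rpl36 (4.70 ± 0.26), Rps14 (4.67 ± 0.24) and Rps29 (4.47 ± 0.20) followed, with adjusted p of 5.2e-09 or less. Snhg8, a host gene of small nucleolar RNAs, rose by 4.58 ± 0.21, Epb41l4aos by 4.40 ± 0.54, and Hbb-bs, which encodes a beta chain of hemoglobin, by 4.39 ± 0.25. Malat1, an abundant nuclear non-coding RNA on chromosome 19 at 5795690 to 5802672, fell most, from 6482 ± 1676 FPKM in input to 292 ± 229.6 in IP on control diet and from 5232 ± 285 to 198 ± 139 on high-fat diet (-4.83 ± 0.33, adjusted p = 1.9e-08). The nuclear RNAs Miat (-2.82 ± 0.28) and Neat1 (-2.67 ± 0.39) fell too. So did the oligodendrocyte genes Ermn (-3.16 ± 0.25) and Mal (-2.65 ± 0.24), Ints6l (-3.03 ± 0.22), Msantd2 (-3.00 ± 0.53), Nktr (-2.73 ± 0.26), Chuk (-2.66 ± 0.25), which encodes a kinase of the NF-kappaB pathway, and Eml5 (-2.65 ± 0.48). Because the strand was not marked, values of genes whose exons overlap a gene on the other strand, such as Malat1, Ermn, Nktr and Eml5, can hold reads of both, and ribosomal protein and globin genes share sequence with pseudogenes or paralogs.

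The ribosomal protein list passed camera at an adjusted p of 1.5e-45 (adjusted p = 0.19 with an estimated correlation), and all 76 members passed when adjusted over the list alone. Rpl41 rose from 102 ± 4.65 to 1622 ± 449 FPKM on control diet (3.78 ± 0.16). The oxidative phosphorylation list passed at 4.6e-25, and it was the only 1 of the 34 lists that also passed with an estimated correlation (adjusted p = 0.0050). Adjusted over the list alone, 59 of its members were higher. Cox6b1 (3.67 ± 0.11), Cox7c (3.44 ± 0.14) and Cox7a2 (2.59 ± 0.10), subunits of cytochrome c oxidase, and Uqcr10 (2.84 ± 0.11), a subunit of complex III, had the smallest p. All 10 mitochondrially encoded genes fell, with a median of -2.37 (adjusted p = 1.8e-05, adjusted p = 0.34 with an estimated correlation), also when adjusted over the list alone. mt-Nd1 fell from 14679 ± 2955 to 4380 ± 3691 FPKM on control diet (-2.52 ± 0.37), and mt-Nd2 (-2.63 ± 0.39), mt-Nd3 (-2.63 ± 0.39) and mt-Co2 (-2.35 ± 0.35) fell by similar amounts.

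Of the glial lists, mature oligodendrocyte and astrocyte markers passed. Oligodendrocyte precursor, tanycyte, and microglia and macrophage markers did not (medians of -0.16, 0.48 and 0.05, the last -0.08 with a pseudocount of 0.1). With quantile normalization the medians were -0.25, 0.25 and 0.37. Of 21 pan-neuronal markers, 17 were higher and 0 lower in IP, with a median of 0.74 (adjusted p = 2.3e-06, adjusted p = 0.19 with an estimated correlation, 17 adjusted over the list alone), but the median was -0.23 after quantile normalization. Vsnl1, a neuronal calcium sensor, rose from 1206 ± 89.0 to 2960 ± 259.7 FPKM on control diet (1.38 ± 0.10). Rbfox3, the NeuN antigen (1.53 ± 0.12), Stmn3 (1.86 ± 0.17) and Thy1 (1.29 ± 0.16, 0.04 and not past the threshold after quantile normalization) rose as well. Of 19 mature oligodendrocyte markers, 14 fell and 1 rose, with a median of -1.03 (-1.58 with quantile normalization, adjusted p = 2.7e-05, adjusted p = 0.33 with an estimated correlation, 15 lower and 1 higher adjusted over the list alone). Mog, a myelin glycoprotein, fell from 21.9 ± 1.60 to 3.42 ± 2.56 FPKM on control diet (-2.22 ± 0.24). Of 19 astrocyte markers, 12 fell and 1 rose, with a median of -1.01 (adjusted p = 0.00011, adjusted p = 0.34 with an estimated correlation, 12 lower and 1 higher adjusted over the list alone). The transporters Slc6a11 (-1.58 ± 0.20) and Slc1a2 (-1.31 ± 0.18), Aldoc (-1.36 ± 0.19) and the water channel Aqp4 (-1.82 ± 0.28) were among them.

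Markers of the thalamus, the choroid plexus and blood cells were also enriched. Of 14 thalamic markers, 8 rose and 2 fell, with a median of 1.04 (0.36 with quantile normalization, adjusted p = 0.0033, adjusted p = 0.34 with an estimated correlation, 8 higher and 2 lower adjusted over the list alone). Tcf7l2 rose from 174 ± 2.34 to 764 ± 165 FPKM on control diet (2.29 ± 0.13), and Ntng1 (1.78 ± 0.12), Lef1 (2.77 ± 0.20) and Ramp3 (2.63 ± 0.20) rose too. Ramp3, a subunit of calcitonin-family receptors, is also on the list of feeding-related receptors. Of 13 choroid plexus markers, 11 rose, with a median of 1.31 (2.24 with a pseudocount of 0.1, adjusted p = 6.4e-04, adjusted p = 0.34 with an estimated correlation, 12 adjusted over the list alone). Ttr, the thyroid hormone carrier of the choroid plexus, rose from 41.5 ± 7.90 to 393 ± 143 FPKM on control diet (3.29 ± 0.43), with Kcne2 (1.82 ± 0.26), Calml4 (2.12 ± 0.36) and Folr1 (2.03 ± 0.45). Of 7 blood cell markers, 5 rose, with a median of 3.56 (adjusted p = 7.6e-04, adjusted p = 0.19 with an estimated correlation, 6 adjusted over the list alone). Of these 4 were globin genes, Hbb-bs, Hbb-bt (3.59 ± 0.29), Hba-a1 (4.02 ± 0.38) and Hba-a2 (3.56 ± 0.35), and 1 is a gene that neurons also express.

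Neuropeptide messages were enriched in part. Of 14 genes of other hypothalamic neuropeptides and secretory proteins, 8 rose, with a median of 0.88 (adjusted p = 0.027, adjusted p = 0.34 with an estimated correlation, 8 higher and 1 lower adjusted over the list alone). Pcsk1n, an inhibitor of prohormone convertase 1 (2.86 ± 0.16), the secreted synaptic proteins Cbln1 (2.25 ± 0.20) and Cbln2 (1.22 ± 0.24), and Chga (1.61 ± 0.16) had the smallest p. Of 22 feeding-related neuropeptides, 8 rose, 1 fell and 13 did not pass, and the list missed the threshold (median 0.82, 0.39 with quantile normalization, adjusted p = 0.059, adjusted p = 0.19 with an estimated correlation, 6 higher and 1 lower adjusted over the list alone). Cck rose from 326 ± 2.35 to 2010 ± 692 FPKM on control diet (2.44 ± 0.15), Sst by 1.32 ± 0.22, Pmch by 1.15 ± 0.23 and Pomc by 1.71 ± 0.40. Sst and Pmch did not pass after quantile normalization, and Pomc did not with a pseudocount of 0.1. Of 18 activity-induced genes, which neurons switch on after firing, 5 rose and 13 did not pass (median 0.54, adjusted p = 0.21, adjusted p = 0.57 with an estimated correlation, 4 adjusted over the list alone). They included Fosb (1.66 ± 0.23), Homer1 (1.06 ± 0.20), Jun (1.29 ± 0.26) and Egr3 (1.37 ± 0.42).

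**Figure D2:**
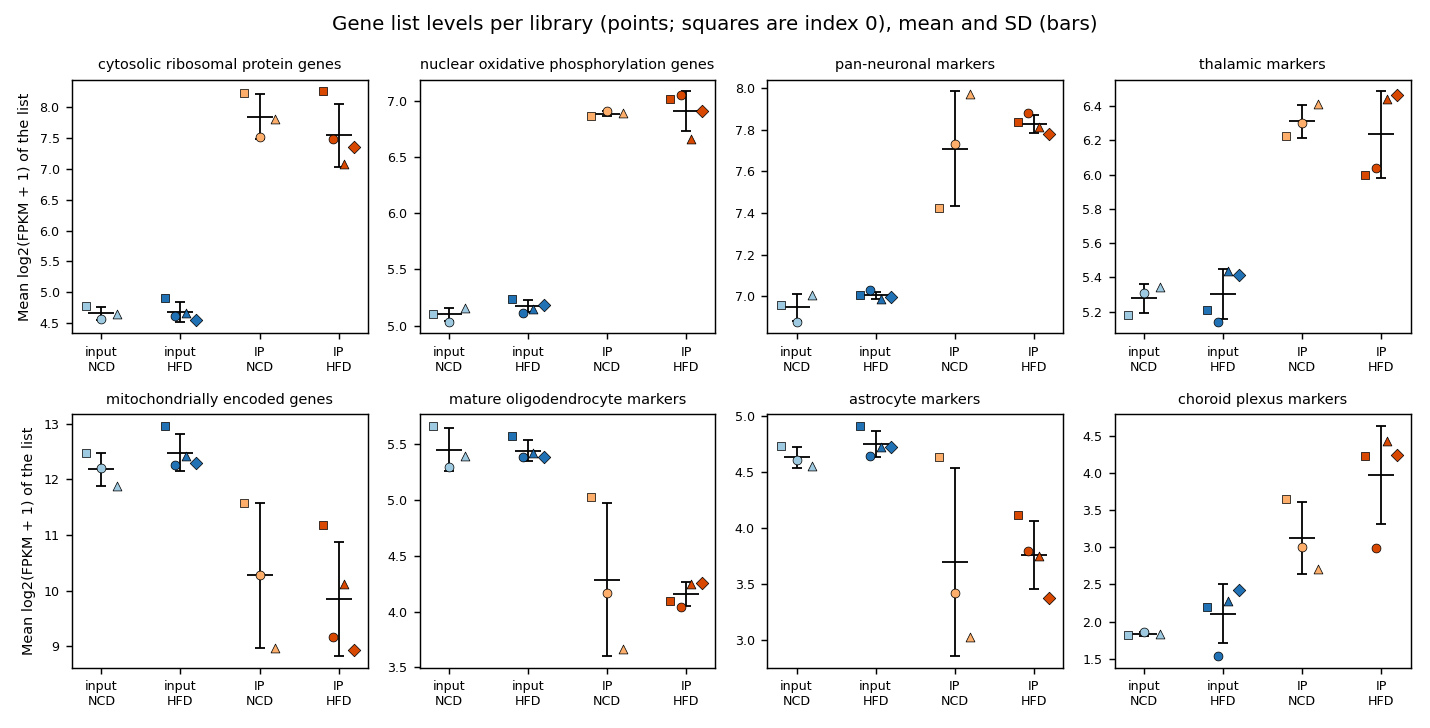
Each panel shows 1 gene list, with the mean log2(FPKM + 1) of its members on the y axis and the 4 groups on the x axis. Points are libraries, shape gives the column index, and the bars are the mean and SD (n = 3 on control diet, n = 4 on high-fat diet). Ribosomal protein levels lie at 4.54 to 4.91 in input and 7.08 to 8.26 in IP. Pan-neuronal levels are higher in IP on this scale, and their median change turns to -0.23 after quantile normalization.

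Enrichment also followed transcript length. Over 12474 genes the change in IP fell with length (Spearman correlation -0.412 across genes, which are not independent replicates), from a median of 1.17 in 1030 genes of up to 1000 bases to -0.62 in 782 genes above 8000 bases.

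**Figure D3:**
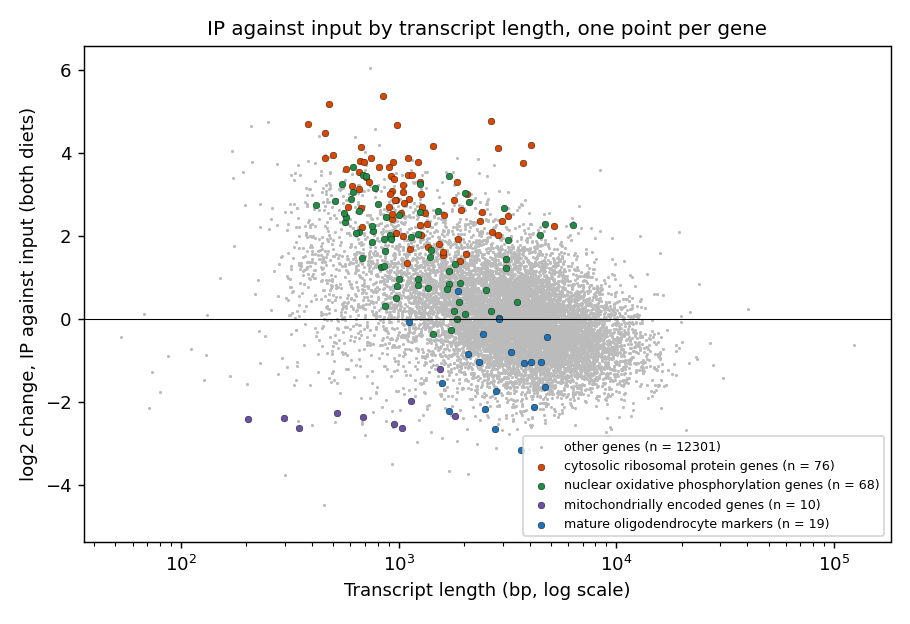
Each gray point is 1 gene, with transcript length in bases on the x axis (log scale) and the log2 change of IP against input over both diets on the y axis. Colored points are members of gene lists and include ribosomal protein and oxidative phosphorylation genes, with medians of 3.01 and 1.94.

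On control diet alone, 3314 of 12484 genes passed limma's test of IP against input, 1963 higher and 1351 lower in IP, but with quantile normalization 44.0% of called genes were higher. Of the ribosomal protein genes, 76 of 76 were higher, with a median of 3.14. Over all 12484 genes, the 3 IP and 3 input libraries did not overlap in 5146 (41.2%), where chance gives 10%. Of these genes, 3237 were past the threshold. Selenow (5.95 ± 0.45), Rpl29 (5.39 ± 0.29), Rps21 (5.33 ± 0.47), Rpl36 (4.83 ± 0.40), Rps19 (4.83 ± 0.32), Snhg8 (4.61 ± 0.32), Hbb-bs (4.61 ± 0.38), Epb41l4aos (4.58 ± 0.82), Hba-a1 (4.56 ± 0.58) and Rps29 (4.53 ± 0.30) rose most. Malat1 (-4.73 ± 0.49), Ints6l (-3.37 ± 0.34), Msantd2 (-3.08 ± 0.81), Ermn (-3.06 ± 0.37), Eml5 (-3.04 ± 0.72), Rev1 (-2.97 ± 0.47), Nvl (-2.91 ± 0.33), Stk38 (-2.87 ± 0.40), Mal (-2.81 ± 0.36) and Zcchc7 (-2.79 ± 0.39) fell most. Of the lists, 10 passed, and 1, oxidative phosphorylation (median 2.01, and 1.11 with quantile normalization), also passed with an estimated correlation (adjusted p = 0.0041). The count was 2031 in a fit on the control-diet libraries alone, 5009 without the IP libraries of index 0, and 2148 without the input library of index 1.

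On high-fat diet, 4197 of 12484 genes passed limma's test of IP against input, 2376 higher and 1821 lower in IP, but with quantile normalization 45.2% of called genes were higher. Of the ribosomal protein genes, 75 of 76 were higher, with a median of 2.87. Over all 12484 genes, the 4 IP and 4 input libraries did not overlap in 5165 (41.4%), where chance gives 2.86%. Of these genes, 3888 were past the threshold. Selenow (6.11 ± 0.39), Rpl29 (5.34 ± 0.25), Rps21 (5.04 ± 0.40), Rps14 (4.87 ± 0.31), Snhg6 (4.84 ± 0.66), Rps19 (4.71 ± 0.28), Rpl36 (4.58 ± 0.35), Snhg8 (4.55 ± 0.28), Rps29 (4.41 ± 0.26) and Rcc1 (4.34 ± 0.33), a nucleotide exchange factor for Ran, rose most. The exons of Rcc1 overlap those of Snhg3, another host gene of small nucleolar RNAs. Malat1 (-4.94 ± 0.43), Nktr (-3.41 ± 0.33), Ermn (-3.26 ± 0.32), Neat1 (-3.06 ± 0.52), Miat (-3.04 ± 0.37), Dusp11 (-3.03 ± 0.29), Rgs5 (-3.01 ± 0.68), Spaca6 (-2.93 ± 0.75), Msantd2 (-2.92 ± 0.70) and Rgs9 (-2.75 ± 0.43) fell most. Of the lists, 11 passed, and 1, oxidative phosphorylation (median 1.79, and 1.12 with quantile normalization), also passed with an estimated correlation (adjusted p = 0.0042). Whether enrichment differs between the diets was tested by the difference of the diet effects, given after the diet comparisons.

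The IP comparison of the diets asks which messages in the precipitated RNA change after 3 days of high-fat diet. With limma 0 of 12484 genes passed the threshold. Pomc and Pnoc had higher values in IP on high-fat diet, while Npy had lower ones and the list of feeding-related peptides did not pass (adjusted p = 0.70, adjusted p = 0.97 with an estimated correlation). Pomc, the precursor of melanocortins, was at 22.8, 15.7, 11.5 and 8.33 FPKM on high-fat diet (index 0 to 3) and at 0, 5.07 and 5.76 on control diet. Pnoc, the precursor of nociceptin, was at 3.11 ± 1.34 FPKM (n = 4) on high-fat diet and 0.409 ± 0.319 (n = 3) on control diet. The log2 differences were 2.09 ± 0.71 for Pomc and 1.5 ± 0.51 for Pnoc, with an adjusted p of 0.81 for each, and neither gene's groups overlapped. Without the IP libraries of index 0 they were 0.96 for Pomc, 1.33 for Pnoc and 0.49 for Agrp. Choroid plexus markers had higher and ribosomal protein genes lower values in IP on high-fat diet, and both lists passed camera at the preset correlation and not with an estimated one (adjusted p = 0.97 each) or by exact permutation of their levels (p = 0.171 and 0.429).

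The 6 genes chosen before the data were examined give the closest view of feeding circuits. Agrp, an appetite-stimulating peptide of arcuate neurons, was at 27.4, 11.4, 0.606 and 8.43 FPKM on high-fat diet and at 0, 1.19 and 6.57 on control diet (1.74 ± 0.97). Npy, expressed by the same neurons, was at 0, 9.96, 13.9 and 22.2 FPKM on high-fat diet and at 7.52, 9.89 and 40.7 on control diet (-1.0 ± 0.98). The differences of Cartpt (0.18 ± 0.46) and of the activity marker Fos (0.56 ± 0.60) were within about their error, and that of Fos was -0.14 with array weights. The mean level of the 6 genes was 2.91 on high-fat diet and 2.06 on control diet, and its difference of 0.84 had an exact permutation p of 0.0286, two-sided, the smallest that 35 splits can give. In input the same difference was -0.05 with an exact permutation p of 0.457. Gene by gene in IP, exact permutation p was 0.0286 for Pomc, 0.0571 for Pnoc, 0.2 for Agrp, 0.343 for Fos, 0.6 for Npy and 0.629 for Cartpt, and Benjamini-Hochberg adjustment over the 6 genes gave 0.171 for Pomc and Pnoc. The positions are chromosome 14, 65400673 to 65425472 for Pnoc, and chromosome 12, 3954951 to 3960642 for Pomc. Agrp lies on chromosome 8 at 105566698 to 105637393, and its exons overlap those of Ctcf on the other strand and of a gene model on the same strand.

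**Figure D4:**
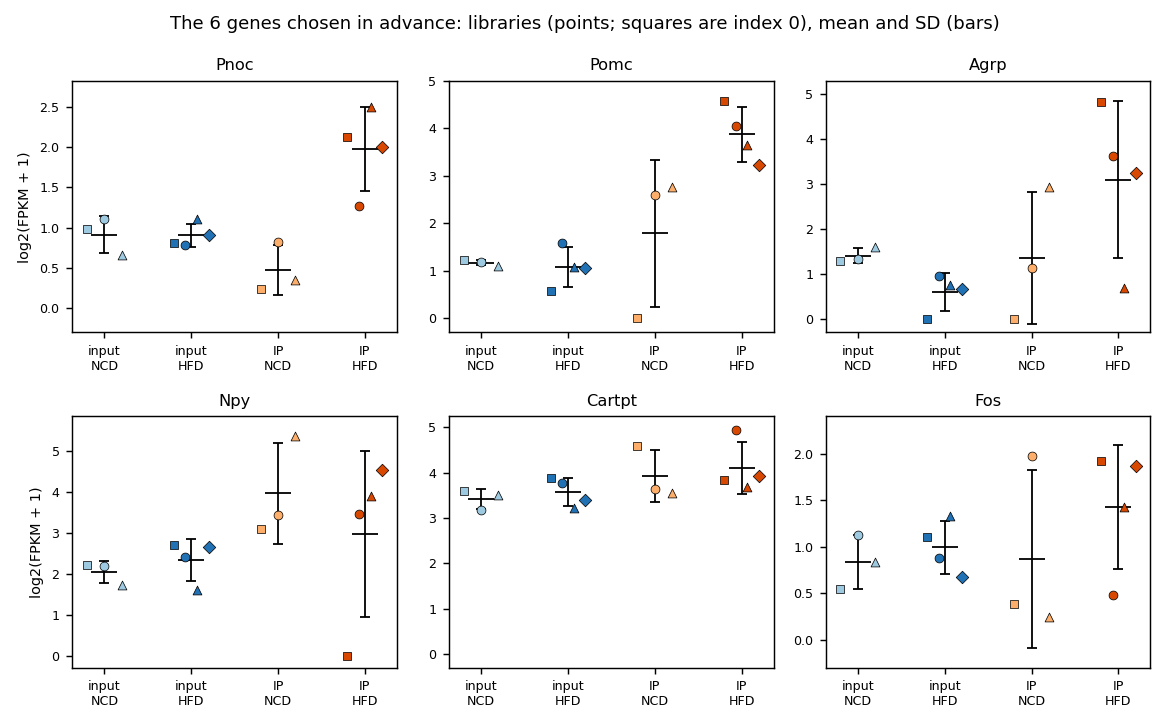
Each panel shows 1 of the 6 genes, with log2(FPKM + 1) on the y axis and the 4 groups on the x axis. Points are libraries, shape gives the column index, and the bars are the mean and SD (n = 3 on control diet, n = 4 on high-fat diet). In IP the 4 high-fat libraries of Pnoc and Pomc lie above the 3 control libraries, and for Agrp the groups overlap.

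Other feeding peptides did not pass either. Crh, the stress hormone precursor, was at 1.32, 1.01, 0 and 0.0947 FPKM on high-fat diet and at 0, 16.4 and 11.5 on control diet. Hcrt, the orexin precursor, differed by 1.09 ± 0.57. Of 18 activity-induced genes 0 passed, with Egr3 at 1.26 ± 0.72, Fosl2 at 0.97 ± 0.61, Fosb at 0.69 ± 0.54 and Nptx2 at -0.90 ± 0.76, which was 0.24 without the IP libraries of index 0. Of 22 feeding-related peptides and 16 fatty acid synthesis genes 0 passed over all genes. Adjusted over the list alone, which was done for each of 34 lists, 1 fatty acid synthesis gene passed, Acly (adjusted p = 0.031), which encodes ATP citrate lyase. In input 3 other lists had 1 such gene each, those of blood cell (adjusted p = 0.0051), endothelial (0.038) and ependymal markers (0.041). Acly was at 78.0 ± 52.7 FPKM (n = 3) on control diet and 19.3 ± 5.12 (n = 4) on high-fat diet in IP (-1.79 ± 0.45, adjusted p = 0.81 over all genes). Slc25a1 (1.01 ± 0.79), Srebf1 (0.58 ± 0.47) and Fasn (-0.64 ± 0.61) of the same list did not pass. Slc25a1 was at -0.020 without the control-diet IP library of index 0.

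The choroid plexus list had a median difference of 0.98 in IP, with 12 of 13 members above 0 (adjusted p = 0.0011, adjusted p = 0.97 with an estimated correlation, and 0 members past the threshold over all genes or adjusted over the list alone). Slc13a4 (1.88 ± 0.65), Folr1 (2.17 ± 0.80), Sostdc1 (1.56 ± 0.61) and Enpp2 (0.98 ± 0.42) had the smallest p. In input its median was 0.27, again at the preset correlation only (adjusted p = 0.59 with an estimated correlation, exact permutation p = 0.286). Of 76 ribosomal protein genes, 8 were above 0, with a median of -0.31 (adjusted p = 9.8e-05, adjusted p = 0.97 with an estimated correlation, and 0 members past the threshold over all genes or adjusted over the list alone). Rpl36 (-1.04 ± 0.41), Rpl17 (-1.14 ± 0.54), Fau (-0.63 ± 0.36) and Rps9 (-0.70 ± 0.43) had the smallest p. Markers of ependymal cells, which line the ventricle, had a median of 0.80 and missed the threshold (6 of 6 above 0, adjusted p = 0.057, adjusted p = 0.97 with an estimated correlation). By exact permutation of list levels, ependymal and tanycyte markers differed by 0.81 and 0.21 (p = 0.0286 each), and Benjamini-Hochberg adjustment over 34 lists gave 0.486, while p was 0.171 for choroid plexus markers and 0.429 for ribosomal protein genes.

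Genes with the smallest p in IP did not pass. Tlr3, a receptor for double-stranded RNA, was at 0.918 ± 0.631 FPKM on control diet and 13 ± 3.60 on high-fat diet (2.89 ± 0.54). The histone H4 methyltransferase Kmt5a (1.80 ± 0.35), Mzt2 (2.52 ± 0.57), S100a10 (2.31 ± 0.56) and the phosphate transporter Slc20a1 (1.72 ± 0.43) also had higher values. Shmt2, the mitochondrial serine hydroxymethyltransferase, was at 7.72 ± 1.97 and 0.368 ± 0.413 FPKM (-2.69 ± 0.52), and Tmem176a (-3.22 ± 0.64), Mtag2 (-2.70 ± 0.59), Trim41 (-2.69 ± 0.60) and the tRNA methyltransferase Mettl1 (-2.09 ± 0.48) also had lower values. The adjusted p was 0.81 for each of these 10 genes, and the smallest of all was 0.110, for Gm17122. Exons of Tlr3, Slc20a1, Shmt2, Tmem176a, Mtag2, Trim41 and Mettl1 overlap genes on the other strand.

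At an unadjusted p below 0.05 limma gave 714 genes in IP (359 higher and 355 lower), and groups did not overlap in 792 genes (6.34%, against 5.71% by chance). The median standard error of a gene's log2 difference was 0.56 in IP. Array weights called 1 gene, the antisense gene model Gm17122. A fit of all 14 libraries called 75 genes, but it takes 1 variance per gene over both fractions. The residual SD of a library was 0.526 to 0.910 in IP and 0.193 to 0.253 in input, so that fit understates the error in IP. At an unadjusted p below 0.05 limma then gave 2209 genes in IP and 28 in input. The 75 calls are therefore not evidence of a diet effect.

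The input comparison of the diets gives the background for IP, in RNA that was not precipitated. Here 0 of 12484 genes passed limma's test, while 6 gene lists had higher values on high-fat diet at the preset correlation of camera and 0 with an estimated one (adjusted p = 0.59 with an estimated correlation for each of the 6). Of 10 mitochondrially encoded genes, 10 were above 0, with a median log2 difference of 0.28 (adjusted p = 0.0052), but 0.04 with quantile normalization. Their level was 12.96 in the high-fat library of index 0 and 12.26 to 12.42 in the other 3. Choroid plexus markers had a median of 0.27 (9 of 13 above 0, adjusted p = 0.014). Unfolded protein response genes (0.12, 17 of 22, adjusted p = 0.0088), astrocyte markers (0.12, 15 of 19, adjusted p = 0.0088), microglia and macrophage markers (0.13, 13 of 16, adjusted p = 0.027) and oxidative phosphorylation genes (0.07, 47 of 68, adjusted p = 0.0088) shifted less. The share of mitochondrial FPKM was 31.3% on high-fat and 27.2% on control diet, with an exact permutation p of 0.371. By exact permutation of list levels, circadian clock genes differed by -0.068 (p = 0.0286), and Benjamini-Hochberg adjustment over 34 lists gave 0.648.

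Members of these lists did not pass one by one, over all genes or adjusted over the list alone. mt-Nd2 was at 12085 ± 1131 FPKM (n = 3) on control diet and 17372 ± 3546 (n = 4) on high-fat diet (0.51 ± 0.22), with mt-Nd3 at 0.46 ± 0.18, mt-Atp8 at 0.34 ± 0.19 and mt-Nd6 at 0.33 ± 0.20. Among choroid plexus markers, Calml4 (0.84 ± 0.24), Otx2 (0.47 ± 0.14), Sostdc1 (0.58 ± 0.28) and Enpp2 (0.27 ± 0.20) had the smallest p. The endoplasmic reticulum chaperones Calr (0.42 ± 0.13) and Hspa5 (0.22 ± 0.08), Sdf2l1 (0.50 ± 0.19) and the stress transcription factor Atf4 (0.21 ± 0.09) did so among unfolded protein response genes. Astrocyte markers among those with the smallest p were Gja1 (0.23 ± 0.09), Mlc1 (0.35 ± 0.14) and Clu (0.32 ± 0.14). Microglial ones were Ly86 (0.45 ± 0.17), C1qc (0.37 ± 0.16) and Aif1 (-0.50 ± 0.26). Among oxidative phosphorylation genes they were Cox7a2 (0.27 ± 0.08), Sdhb (0.33 ± 0.11), Atp5e (0.38 ± 0.15) and Ndufs7 (-0.23 ± 0.09).

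Of the 6 genes chosen in advance, Agrp, Pomc, Pnoc and Fos lay near 1 FPKM in input, and Npy and Cartpt higher. Agrp was at 0, 0.949, 0.684 and 0.595 FPKM on high-fat diet and at 1.44, 1.51 and 2.02 on control diet (-0.81 ± 0.23, adjusted p = 0.84, exact permutation p = 0.0571). Pomc (-0.09 ± 0.22), Pnoc (-0.01 ± 0.16), Npy (0.29 ± 0.27), Cartpt (0.14 ± 0.18) and Fos (0.16 ± 0.21) differed by less than 1.5 standard errors, and the sign of Pnoc and Pomc depended on single libraries. Nab1, a corepressor of EGR transcription factors, was at 12 ± 1.43 FPKM on control and 19.8 ± 1.21 on high-fat diet (0.68 ± 0.10, adjusted p = 0.43). Cpe, which processes neuropeptide precursors (0.56 ± 0.10), the splicing factor Hnrnph1 (0.46 ± 0.08), Eps8l1 (0.78 ± 0.14) and Hba-a1 (0.93 ± 0.19) also had higher values, with an adjusted p of 0.84 each. Bola3, an iron-sulfur cluster assembly factor, had the smallest p and was at 10.6 ± 0.932 and 5.48 ± 0.613 FPKM (-0.84 ± 0.12, adjusted p = 0.43). Usp3 (-0.74 ± 0.15), Smim8 (-0.91 ± 0.19), Zfp771 (-1.03 ± 0.24) and the kinase Stk11 (-0.43 ± 0.11) had lower values, with an adjusted p of 0.84 each.

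At an unadjusted p below 0.05 limma gave 714 genes in input (386 higher and 328 lower), and groups did not overlap in 849 genes (6.80%, against 5.71% by chance). The median standard error was 0.15, against 0.56 in IP. Without the high-fat input library of index 0, limma called 1 gene, the processed pseudogene Gm14303, which that library lists at 0.

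The difference of the diet effects tests whether IP responds to the diet otherwise than input. Of 12484 genes 1 passed limma's test, the gene model Gm17122 (adjusted p = 0.0053), and it was singled out after its values were seen. It is an antisense RNA on chromosome 5 at 113842601 to 113843116 whose exons overlap those of Coro1c on the other strand. In IP it was at 12.9, 11.5 and 28.9 FPKM on control diet and below 0.001 in the 4 high-fat libraries, while in input it was at 0.989 to 1.71 on control and 2.02 to 14.4 on high-fat diet. No fold is given, since values near 0 can be failed estimates of the authors' tool, and it was not called with array weights. With FPKM below 0.001 as missing it has no value in high-fat IP, so it could not be tested. Coro1c was at 26.5 ± 16.0 and 10.3 ± 4.07 FPKM in IP on control and high-fat diet.

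The list of ribosomal protein genes had lower values in this difference at the preset correlation only, with a median of -0.36 and 10 of 76 above 0 (adjusted p = 7.0e-04, adjusted p = 0.98 with an estimated correlation). It was the only list to pass, while 3 lists passed with same-index columns as a fixed replicate block. Rpl17 (-1.33 ± 0.53), Rps27a (-1.21 ± 0.67), Rpl27 (-0.56 ± 0.32) and Rpl32 (-0.57 ± 0.34) had the smallest p, and 0 members passed over all genes or adjusted over the list alone. Among feeding-related peptides, Pnoc differed by 1.51 ± 0.46 (adjusted p = 0.59), Pomc by 2.18 ± 0.80 (0.66), Agrp by 2.55 ± 1.11 (0.73) and Nmb by -1.15 ± 0.57 (0.74). Npy (-1.29 ± 1.18), Cartpt (0.04 ± 0.48) and Fos (0.40 ± 0.63) had errors near the size of the value. Acly passed when adjusted over the list alone (adjusted p = 0.049) and not over all genes (-1.73 ± 0.49, adjusted p = 0.54). Of the genes with the smallest p that did not pass, Tlr3 (2.84 ± 0.46), Kmt5a (1.90 ± 0.37), the mitochondrial RNA polymerase Polrmt (2.84 ± 0.60), Zfyve27 (1.98 ± 0.42) and Zdhhc24 (1.59 ± 0.34) had higher values, with adjusted p of 0.10 to 0.34. Shmt2 (-2.66 ± 0.44), Mettl1 (-2.21 ± 0.43), Mtag2 (-3.04 ± 0.60), Tmem176a (-3.18 ± 0.63) and Slc37a1 (-2.29 ± 0.47) had lower values, with adjusted p of 0.10 to 0.30. At an unadjusted p below 0.05 there were 845 genes (416 higher and 429 lower), and groups did not overlap in 839 (6.72%, against 5.71% by chance). The count of called genes was 12 without the IP libraries of index 0, 7 without the control-diet IP library of index 0, and 128 without the control-diet IP library of index 1.

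The authors' own test of the same question, on IP to input ratios, marks 418 of 14531 entries at an unadjusted p below 0.05 (2.88%), 245 higher and 173 lower on high-fat diet. After Benjamini-Hochberg adjustment, computed here with limma's threshold of 0.05, 0 remained, with a smallest adjusted p of 0.277. Of the 418 entries, 372 were tested here, 370 had the same sign as the difference of the diet effects and 220 an unadjusted p below 0.05 in it. Both tests use the same FPKM values, and the entries were selected by their p in the same contrast, so this overlap is not independent support. In 172 entries the authors' log2 value is beyond 20 in size, where a ratio was taken with a value near 0.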

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

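The tests of mitochondrial composition, arcuate tissue, carry-over, the neighbouring gene of Igsf5 and the splits of the authors' ratios were chosen after the result was seen. Genes are named here by the rule given with the methods, and Gm17122 and Igsf5 were chosen after their values were seen.

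Ribosomal protein and oxidative phosphorylation messages were far higher in IP than in input, and both kinds of message are short. In 10000 random lists matched for length the median was 0.62 (central 95% 0.33 to 0.94) against the real 3.01 for ribosomal protein genes. It was 0.56 (0.28 to 0.89) against 1.94 for oxidative phosphorylation genes. On this scale, length as annotated was therefore excluded as the whole cause. That length is of each gene's longest transcript, which can exceed the message present, and genes of up to 1000 bases had a median of 1.17. Lists were not matched for expression level. The matching was not run with quantile normalization, where the oxidative phosphorylation median was 1.12. Lists matched for GC content had medians of 0.034 and 0.028, which excludes GC content as the whole cause too. At an unchanged summed FPKM, the smaller mitochondrial share would raise every other gene by 0.39. That lies below the lower quartiles of the lists (2.36 and 0.87), so under this condition the share is excluded as the whole cause. Binding to the antibody or beads without phosphorylated S6 stays open, since no precipitation with a control antibody was analysed here, and no biological explanation was tested.

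Pnoc, Pomc and Agrp had higher values in IP on high-fat diet, though none passed alone (Benjamini-Hochberg adjusted exact permutation p of 0.171, 0.171 and 0.4). Npy was lower (-1.0, unadjusted p = 0.6) and Cartpt near 0 (0.18, unadjusted p = 0.629). For the mean of the 6 genes chosen in advance, the exact permutation p was 0.0286, the smallest possible. Since 2 of 34 lists in IP and 1 in input reached that p too, a chance split of the libraries is not excluded. The mean was not tested without the control-diet IP library of index 0, where Pomc and Agrp were at 0. More arcuate tissue in the high-fat pools cannot be told apart, because the input values of the 3 genes lie near 1 FPKM, where changes are understated. The largest upper 95% limit of their input change was 0.41, and Agrp was lower in input (-0.81, 95% limits -1.32 and -0.29). The better expressed Npy and Cartpt differed in input by 0.29 (exact permutation p = 0.4) and 0.14 (exact permutation p = 0.543). Levels of tanycyte markers differed in input by -0.014 (exact permutation p = 0.686) and those of ependymal markers by 0.23 (exact permutation p = 0.2). These input values go both ways and do not decide whether the high-fat pools held more arcuate tissue. Of 34 lists tested, those of tanycyte and ependymal markers had higher levels in IP in 4 of 4 high-fat libraries (exact permutation p = 0.0286 each), but neither passed after Benjamini-Hochberg adjustment (0.486), and choroid plexus markers had p = 0.171, so they leave this open. The share of genes at 0 in the index 0 libraries cannot be told apart either, since without them the differences were 1.33 ± 0.56 for Pnoc, 0.96 ± 0.48 for Pomc and 0.49 ± 0.96 for Agrp, with a median of 0.96 against a limit of 0.87. A response of cells expressing these 3 genes to the diet may be the cause and stays an untested hypothesis.

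The IP libraries of index 0 held the most mitochondrial RNA and the most entries at 0 in each diet. Carry-over of input RNA as the whole cause was excluded, because it lowers ribosomal protein levels, and these lay 0.78 above the highest other IP library on high-fat diet and 0.43 on control diet. Part of it stays open, since most levels of lists with a negative median in IP against input were raised, as carry-over predicts. In the control-diet library of index 0 the level of astrocyte markers was 4.64 against 3.42 and 3.03. Oligodendrocyte markers were at 5.02 against 4.17 and 3.67 there, and nuclear-retained RNAs at 6.33 against 5.89 and 5.34. On high-fat diet astrocyte markers were at 4.11 against 3.38 to 3.80 and nuclear-retained RNAs at 6.63 against 5.12 to 5.32. Only oligodendrocyte markers were not raised there (4.09 against 4.04 to 4.26). Fewer distinct molecules stay open as a contribution. Genes at 0 were 152 times (high-fat diet) and 134.5 times (control diet) as frequent in the lowest 25% as in the highest 25% of genes by level. The gradient was steeper in every other IP library, at 181 times in the high-fat library of index 2. The remaining IP libraries held no gene at 0 in the highest 25%. The gradient therefore does not set the libraries of index 0 apart and cannot decide this. No biological explanation was tested, because the index has no meaning in the labels.

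Single libraries lay far from the 3 others of their group in 25 of 380 groups tested, where chance flags about 1 in 20 groups. Only groups of 4 libraries, those on high-fat diet, were tested, so control-diet libraries could not be flagged. The value given is the gap to the nearest library over the range of the group. In high-fat input of index 0 these were Rpl27 (0.982), Tlr3 (0.953), Usp3 (0.930), mt-Nd1 (0.922), Vsnl1 (0.915), the level of feeding-related peptides (0.864) and the mitochondrial share (0.830). In high-fat input of index 1 they were Ttr (0.915), Tcf7l2 (0.894) and Cpe (0.848), and of index 3 Hbb-bt (0.909) and Trim41 (0.897). In high-fat IP of index 0 they were Ermn (0.926), Gas5 (0.884), Rpl32 (0.867), the level of nuclear-retained RNAs (0.867), Mlc1 (0.858), Rps19 (0.855), Stk38 (0.838) and Slc1a2 (0.838). In high-fat IP of index 1 they were S100a10 (0.870) and the level of choroid plexus markers (0.854), and of index 2 Msantd2 (0.915), Hbb-bt (0.871) and Tmem176a (0.866).

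The diet effect differed between IP and input for Gm17122 (adjusted p = 0.0053) and for the list of ribosomal protein genes (adjusted p = 7.0e-04, adjusted p = 0.98 with an estimated correlation). Chance cannot be excluded for either count, since 6 of 35 splits of the libraries called as many genes (1 in the real split, at most 1 in another) and 23 of 35 as many lists (1 and at most 4).

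Other splits of the libraries were also counted for the remaining results. For the diet in IP, chance cannot be excluded for the 714 genes at an unadjusted p below 0.05 (4 of 35 splits as many, at most 1177) or the 2 lists (21 of 35, at most 8). For the diet in input it cannot be excluded for the 714 genes (7 of 35, at most 1200) or the 6 lists (14 of 35, at most 12). For IP against input over both diets, chance was excluded for the 5482 genes (1 of 100 splits, the real one, with at most 2009 in another). On high-fat diet it was excluded for the 4197 genes (1 of 35, at most 0 in another). As many lists as the real 10 passed in 8 of 100 splits (at most 12), and as many as the real 11 in 5 of 35 (at most 12). Splits that leave most IP libraries on one side still hold part of the IP difference. These counts of lists therefore cannot tell whether chance explains the lists. On control diet 10 splits are too few for a test, with 3314 genes in the real split and at most 0 in another (1 of 10 as many), and 10 lists against at most 8 (1 of 10). For the authors' 418 entries chance cannot be excluded (5 of 35, at most 617).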

How the results depend on the processing

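The fits without the IP libraries of index 0 and with FPKM below 0.001 as missing, the block on the column index in the diet comparisons, and the alternatives for list levels were chosen after the data were seen. Of the values of named genes under an alternative, 4855 kept their direction and their side of the threshold, 27 newly passed it, 7 no longer passed and 23 reversed. The count of genes for IP against input over both diets was 4685 to 6202 with 1 library left out, and on high-fat diet 3265 to 4320.

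On control diet the count was 2031 in a fit on that diet alone and 5009 without the IP libraries of index 0. It was 2148 to 3991 with 1 library left out, lowest without the input library of index 1. For the diet in IP it was 1 with array weights and 0 to 0 with 1 library left out. In the fit on all 14 libraries, which understates the error in IP, it was 75. For the diet in input it was 1 with FPKM below 0.001 as missing and 0 to 1 with 1 library left out, the 1 being Gm14303 without the high-fat library of index 0. For the difference of the diet effects it was 0 with array weights, 0 with FPKM below 0.001 as missing, where Gm17122 has no value left in high-fat IP, and 12 without the IP libraries of index 0. It was 1 to 128 with 1 library left out, namely 7 without the control-diet IP library of index 0 and 128 without that of index 1. The cause was not tested.

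With an estimated correlation, 0 lists passed for the diet in IP, 0 for the diet in input and 0 for the difference of the diet effects, and 1 passed for IP against input over both diets, 1 on control diet and 1 on high-fat diet. At the preset correlation, 5 lists passed for the diet in IP without the IP libraries of index 0, against 2 with them. A larger correlation between genes widens the test by construction, but it need not be the only reason. In simulated IP libraries, whose genes were drawn independently, the adjusted p of camera for a raised list rose from 4.8e-11 to 0.018. A list that does not pass with an estimated correlation is therefore not by itself evidence of correlated genes. The number of lists whose level differed between the diets at an unadjusted exact permutation p below 0.05, 3 over both fractions, was 3 with a pseudocount of 0.1 and 2 with median-ratio scaling.

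These values changed sign, each in a gene that had not passed except Hlf. With array weights Fos was -0.14 for the diet in IP and -0.31 for the difference of the diet effects, and Pnoc was 0.068 for the diet in input. Without the IP libraries of index 0, Nptx2 was 0.24 for the diet in IP, and Fos was -0.00863 and Scd2 0.0047 for the difference of the diet effects. With quantile normalization Hlf was -0.17 for IP against input. With 1 library left out, the diet in IP was -0.10 to 0.51 for Cartpt and -0.020 to 1.67 for Slc25a1. The diet in input was -0.14 to 0.082 for Pnoc and -0.26 to 0.075 for Pomc, and the difference of the diet effects was -0.25 to 0.37 for Cartpt and -0.57 to 0.015 for Scd2. The cause was not tested.

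A pseudocount of 0.1 moved the median of all genes for IP against input over both diets from 0.0046 to -0.10, and on control diet from 0.01 to -0.09. Median-ratio scaling and quantile normalization moved it by less than 0.1 in each comparison. The planned block on the replicate numbers of the labels was not run for the 2 diet comparisons, because the columns carry none. The read depth is unknown, and its effect on low genes was not tested.

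As a replicate block, columns of the same index were taken as pairs. Residuals of the 7 same-index pairs correlated at -0.0043 to 0.058, 0 of them above 0.1, although 6 of 7 IP libraries correlated best with the input of their own index. With a fixed block the counts were 5174 over both diets, 2852 on control diet and 3773 on high-fat diet, with a random block 5540, 3395 and 4275, and 1 gene was called for the difference of the diet effects with either. With a fixed block 3 lists passed for that difference. With the column index as a replicate block in the diet comparisons, limma called 0 genes in IP (562 at an unadjusted p below 0.05) and 0 in input (806), and 2 and 6 lists passed. In input, choroid plexus markers and microglia and macrophage markers then did not pass, while ribosomal protein genes and endothelial markers did.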

Other observations

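The test of the neighbouring gene of Igsf5 was chosen after the result was seen, and the gene lists were set before the data were examined.

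Stress and hormone-responsive lists did not pass in IP against input over both diets, although single members did. Of 22 unfolded protein response genes, 4 rose, 2 fell and 16 did not pass (median 0.21, adjusted p = 0.54, adjusted p = 0.57 with an estimated correlation). Atf4 rose from 15.1 ± 0.613 to 96.7 ± 30.8 FPKM on control diet (2.62 ± 0.16), Manf (1.64 ± 0.24) and Sdf2l1 (1.26 ± 0.28) rose, and Dnajc3 fell (-1.38 ± 0.29). Of 16 glucocorticoid-responsive genes, 4 rose and 1 fell (median 0.45, adjusted p = 0.21, adjusted p = 0.42 with an estimated correlation), with the metallothioneins Mt1 (2.74 ± 0.21) and Mt2 (2.09 ± 0.17), Klf9 (1.20 ± 0.12) and Tsc22d3 (0.92 ± 0.19) rising. Of 19 circadian clock genes, 5 rose and 5 fell (median 0.01, and -0.39 with a pseudocount of 0.1). Dbp (2.22 ± 0.25), Hlf (0.88 ± 0.13, reversed with quantile normalization) and Nr1d1 (0.92 ± 0.22) rose and Tef (-1.25 ± 0.24) fell. Of 20 genes of fatty acid oxidation and PPAR targets, 2 rose and 6 fell (median -0.64), with Ppargc1a (1.59 ± 0.12) and Ucp2 (1.67 ± 0.32) rising and Acadl (-1.25 ± 0.27) and Slc25a20 (-1.11 ± 0.22) falling.

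Synaptic messages went both ways. Of 32 postsynaptic and glutamate receptor genes, 11 rose and 4 fell (median 0.21, and -0.02 with quantile normalization), among them Dlg4, which encodes PSD-95 (2.33 ± 0.12), Nlgn2 (1.85 ± 0.13), Cacng2 (1.41 ± 0.12) and Nlgn1 (1.01 ± 0.16). Of 19 GABA-A and glycine receptor genes, 6 rose and 8 fell (median 0.19, -0.23 with a pseudocount of 0.1 and -0.47 with quantile normalization), with Gabra4 rising (1.11 ± 0.13, not past the threshold with quantile normalization) and Gabra2 (-1.42 ± 0.13) and Gabrb1 (-0.90 ± 0.15) falling. Of 25 feeding-related receptors, 3 rose and 4 fell (median -0.18, -0.29 with a pseudocount of 0.1 and -0.01 with quantile normalization). Cnr1, the cannabinoid receptor (-1.05 ± 0.18), Npy2r (-1.14 ± 0.28) and Ntrk2 (-0.70 ± 0.17) fell. Of 8 nuclear-retained RNAs, 5 fell and 2 rose (median -1.55), and the 2 were Gas5 (3.45 ± 0.21), a host gene of small nucleolar RNAs, and Snhg14 (2.19 ± 0.18).

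The entry named Igsf5 was among the most abundant, at 1283 ± 59.7 FPKM in input and 12545 ± 2131 in IP on control diet. It may hold reads of the neighbouring gene Pcp4, because a second annotated gene named Igsf5 covers 57975 bases of Pcp4 and Pcp4 has no entry of its own.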
